A study of Arabidopsis with 6 samples.

How the data were processed

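The study measured transcript levels in the aerial parts of soil-grown Arabidopsis thaliana plants with Affymetrix ATH1 arrays. Per the labels' protocols, plants were grown for 21 days at 22 °C under 8 h of light and 16 h of dark, total RNA was isolated with TRIzol and cleaned on RNeasy columns, and biotin-labelled cRNA was made by oligo(dT)-primed one-cycle synthesis. There were 3 arrays of wild type (Col-3) and 3 of the apum23 mutant. The series design names the mutant as apum23-1 and calls the samples independent, while the descriptions of apum23 replicates 2 and 3 carry the names apum23-2 and apum23-3. Whether these are other alleles or replicate numbers is not given in the sources used here, so all 3 arrays were kept as 1 group and replicate 1 was also tested alone.

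The deposited values are log2 probe set intensities, and per the submitters' processing notes RMA and limma were used, with no version given. The deposited log2 values were used as they stand. They do not share 1 distribution: array medians were 5.34, 5.77 and 5.94 in wild type and 5.70, 5.75 and 6.10 in apum23, so a quantile step across these 6 arrays is not in the values. In the limma fit of these values the prior degrees of freedom were infinite (6.11 after centring each array on its median, 7.27 after quantile normalization), the standard error of a log2 fold change was 0.22 for every probe set, and the call amounted to a threshold on the fold change, with 0.66 the smallest absolute log2 fold change called. Quantile normalization of the deposited values was the main alternative, with a median standard error of 0.11, and the report gives the calls it adds or removes among the named genes and lists.

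Of the 22810 probe sets, the 64 control probe sets were left out and 22746 were tested. The table used for gene names pairs 13513 of them with 1 gene and 503 with several, and 8730 are unnamed here. Of the 1-gene probe sets 13436 were matched to the RefSeq gene table of assembly TAIR10.1, which gave current symbols. They stood for 13355 genes, of which 147 had several probe sets, and the brightest over the 6 arrays stood for the gene. No probe set was named from a row with several genes. The table names no probe set for the mutated gene APUM23 itself, so its level is not analysed here and the genotype labels have no check from it. The gene lists are thinly covered for the same reason.

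Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without a block, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a call at an adjusted p under 0.05. The number of arrays limits the precision. Nothing in the sources used here says how plants were pooled into samples, so p-values refer to these samples only. In the main fit they rest on 1 spread pooled over all probe sets, not on each gene's own spread. The spiked-in control bioC-3, low on wild-type replicate 1 alone, shows this. Its limma adjusted p was 3.08e-12 as deposited and 0.325 after quantile normalization. Named genes were the 12 with the largest rise and the 12 with the largest fall among called 1-gene probe sets whose groups did not overlap, up to 2 rising and 2 falling called members of each gene list, the member with the largest change of each list without a call, and any measured member of a marker list. In all, 28 gene lists were used, of which 23 had measured members and 14 had the 3 members needed for a test. The plastid-encoded and mitochondrion-encoded lists were built from the chromosome of the gene rather than from a locus prefix, because the gene table does not carry those prefixes. Lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

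The fit was tested on simulated data for 22746 probe sets with the arrays' own median offsets. Changes were added only to probe sets with a mean above 5, and noise was drawn independently for each probe set. The fit recovered 0% of changes of 0.5 on the log2 scale, 43.5% of changes of 1 and 100% of changes of 2, with 9 false calls. After quantile normalization the shares were 32.4%, 83.9% and 100%, with 5 false calls. These shares do not cover dimmer probe sets. Shifts that many probe sets share beyond the array medians were not simulated, so false calls in the real data may be more. Alternatives tried were the replicate number as a block, quantile normalization, median centring, a filter on the dimmest 40% of probe sets, other variance models, array weights, each array left out in turn, other thresholds, other set tests and other ways to choose probe sets. Quantile normalization without wild-type replicate 1, quantile normalization with an estimated correlation or with fry, median centring with a fold change threshold, and quantile normalization for the control probe sets were added after seeing the data.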

Results

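The study asked which transcripts differ between apum23 plants and their wild type (Col-3) under normal growth. APUM23 is a nucleolar protein of the Pumilio RNA-binding family with a role in the processing of ribosomal RNA precursors. Aerial parts of plants grown on soil for 21 days were measured on ATH1 arrays, 3 per genotype. Arrays of 1 genotype correlated at 0.991 to 0.996 over all probe sets, and arrays of different genotypes at 0.982 to 0.987. Wild-type replicate 1 stood apart in its spiked-in hybridization controls, with a mean log2 intensity of 5.36 against 9.42 to 9.74 on the other 5 arrays, and it had the lowest array median.

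Genes with the largest rises in apum23 were mostly dim in wild type. In wild type 7 of the 12 were within or below the range of the arrays' lower quartiles (3.41 to 3.84), where intensities are close to the background and a log2 change has an uncertain size. These were AT2G04050 (3.22), AT5G60250 (3.53), AT3G55920 (2.91), AT5G24240 (3.80), AT1G17960 (3.69), AT5G11410 (3.07) and AT2G18720 (3.65). AT2G04050, which encodes a MATE-type efflux protein, rose from 3.22 ± 0.20 to 8.87 ± 0.42 (log2 intensity, SD, n = 3; adjusted p = 9.0e-135). AT5G60250, a RING-type zinc finger gene, rose by 4.22 on the log2 scale, the cyclophilin gene AT3G55920 by 4.11 and the AAA-type ATPase gene AT2G18190 by 3.89. Next came AT5G24240 (phosphatidylinositol kinase family) at 3.49, AT1G17960 (threonyl-tRNA synthetase family) at 3.22 and the protein kinase gene AT5G11410 at 3.21. AT2G18720, of a translation factor family, rose by 2.90, AT1G07050, with a CCT motif, by 2.85, and AT3G45730 by 2.67. The PLATZ transcription factor gene AT5G46710 was already at 7.00 ± 0.47 in wild type and rose to 9.84 ± 0.20. AT2G21640, known as a marker of oxidative stress, rose by 2.65. For these 12 genes the 3 apum23 arrays all lay above the 3 wild-type arrays.

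The falls were smaller. The thionin gene AT1G66100 had the largest, from 11.12 ± 0.38 to 8.81 ± 0.14, a log2 change of -2.32 (adjusted p = 4.18e-22), and a second thionin gene, THI2.2, changed by -1.59. CYP71B22, a cytochrome P450 gene, changed by -2.06, AT5G22430 by -1.84 and the glutaredoxin gene AT2G47880 by -1.60. QQS, a gene with a role in starch accumulation, went from 9.11 ± 0.01 to 7.57 ± 0.29. ALN, which encodes allantoinase of purine breakdown, changed by -1.45, as did the glycosyltransferase gene AT3G55710, while AT5G09300, of branched-chain amino acid breakdown, changed by -1.47. The F-box gene AT3G23880 changed by -1.36, AT2G20870 by -1.34 and AT5G16140, a peptidyl-tRNA hydrolase gene, by -1.29.

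**Figure D1:**
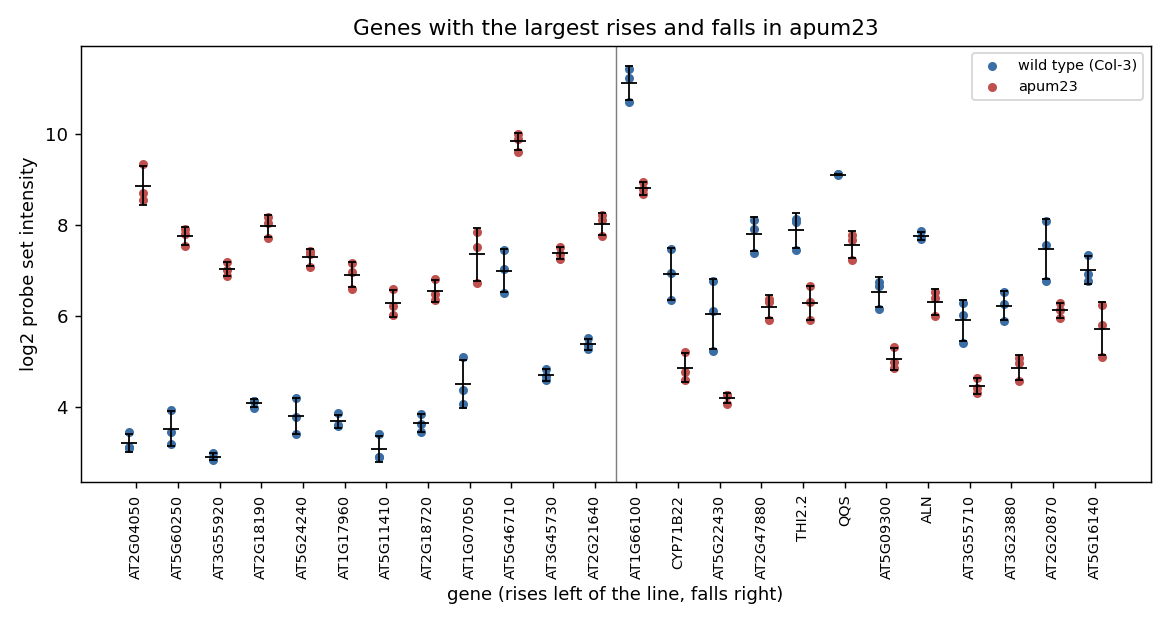
Log2 probe set intensity of the 12 genes with the largest rises and the 12 with the largest falls, one point per array, with the mean and SD of 3 wild-type and 3 apum23 arrays. The groups do not overlap for any gene shown, and AT2G04050 moves from 3.22 to 8.87.

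In all, limma called 1522 probe sets, 1208 higher and 314 lower in apum23, so that 79.4% of the calls were higher. With an absolute log2 fold change of 1 or more, 395 were higher and 57 lower, and after quantile normalization 285 and 97. The balance of directions differed between scalings, which also changed limma's variance estimates. After quantile normalization 4481 probe sets were called, 2205 higher and 2276 lower (49.2% higher), with arrays centred on their medians 1196 were higher and 1801 lower (39.9% higher), and quantile normalization moved the median log2 fold change of all probe sets from 0.08 to -0.02. The balance also moved with single arrays left out, from 779 higher and 851 lower without wild-type replicate 1 to 1699 and 143 without wild-type replicate 3. The total was 861 without wild-type replicate 2 (766 higher, 95 lower), and 880 (807 and 73), 898 (782 and 116) and 852 (561 and 291) without apum23 replicates 1, 2 and 3. Of the 1522, 1464 were called in the same direction after quantile normalization. The groups did not overlap in 1344 of the 1522, and in 14.2% of all tested probe sets, where chance gives 10%.

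Genes for making ribosomes rose as a group. Of 36 measured ribosome biogenesis factors (68 on the list), 33 rose, 0 fell and 3 did not pass the test, and 35 rose when adjusted over the list alone. The median log2 fold change was 1.01, which is 0.93 above that of all probe sets. AT3G12860, of the NOP56 family of small nucleolar RNA-protein particles, rose from 4.77 ± 0.21 to 6.80 ± 0.20, and AT3G22660, of the EBP2 rRNA processing family, from 6.95 ± 0.31 to 8.39 ± 0.17. The camera test gave an adjusted p = 2.65e-42, and adjusted p = 0.499 with an estimated correlation (0.74 here, 0.057 after quantile normalization). On quantile-normalized values, 35 rose, the median was 0.92, and adjusted p = 0.00865 with an estimated correlation. With apum23 replicate 1 as the only mutant array, the median was 0.81.

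Cytosolic ribosomal protein genes rose as well. Of 129 measured (223 on the list), 56 rose, 0 fell and 73 did not pass the test, with 127 of the 129 log2 fold changes above 0 and 85 called when adjusted over the list alone. The median was 0.61, or 0.53 above that of all probe sets. AT2G40010, a gene of the P0 stalk protein family, rose from 6.40 ± 0.39 to 8.80 ± 0.29, and AT5G59240, an S8 family gene, from 4.67 ± 0.53 to 6.88 ± 0.25. The camera test gave an adjusted p = 1.74e-35, and adjusted p = 0.561 with an estimated correlation (0.72 here, 0.0083 after quantile normalization). After quantile normalization 103 members rose and 0 fell, with a median of 0.55 and adjusted p = 0.00171 with an estimated correlation. The count was 37 without wild-type replicate 2, 30 without apum23 replicate 2 and 26 without apum23 replicate 3. With apum23 replicate 1 as the only mutant array, the median was 0.45.

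**Figure D2:**
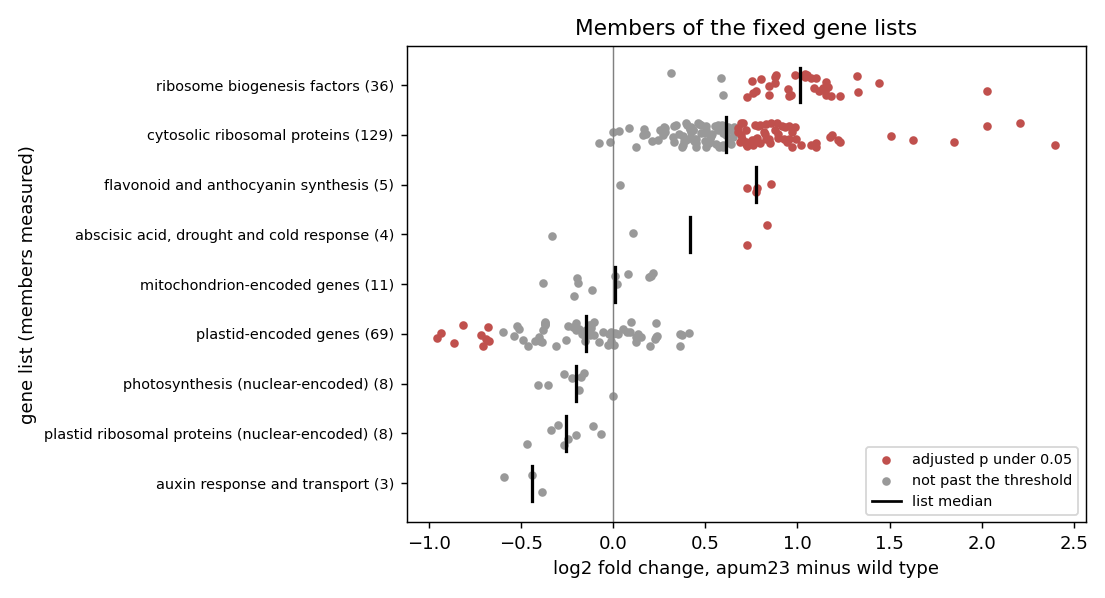
Log2 fold change (apum23 minus wild type) of each measured member of 9 gene lists, one point per gene, red where limma's adjusted p was under 0.05, with the list median as a bar. Medians are 1.01 for ribosome biogenesis factors and 0.61 for cytosolic ribosomal proteins, and -0.15 for plastid-encoded genes, where 9 of 69 fell.

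Plastid-encoded transcripts were lower or did not pass the test. Of 69 genes, 0 rose, 9 fell and 60 did not pass, with a median of -0.15, and after quantile normalization 0 rose and 17 fell. The number that fell was 1 without wild-type replicate 2, 3 without apum23 replicate 1 and 1 without apum23 replicate 2, and the median was -0.069 without wild-type replicate 2 and -0.24 without apum23 replicate 3. psaC was not called without wild-type replicate 2, nor ndhK without apum23 replicate 2. The NAD(P)H dehydrogenase subunit gene ndhK went from 7.97 ± 0.12 to 7.02 ± 0.26 and the photosystem I gene psaC from 9.22 ± 0.27 to 8.29 ± 0.23. The list's camera test gave an adjusted p = 4.91e-08, and adjusted p = 0.663 with an estimated correlation. Oligo(dT) priming captures plastid transcripts poorly, as they mostly lack long poly(A) tails. The 8 measured nuclear genes for plastid ribosomal proteins had 0 calls and a median of -0.26 (camera adjusted p = 0.00883, and adjusted p = 0.663 with an estimated correlation). That median was -0.42 without wild-type replicate 1, and -0.15 without wild-type replicate 3 or without apum23 replicate 1. AT4G17560 had the largest difference of these, -0.47 (adjusted p = 0.273). After quantile normalization 3 of the 8 fell: AT4G17560 (-0.50, limma adjusted p = 0.0121) and, named after their values were seen, AT3G13120 (-0.41) and AT5G65220 (-0.32). The 8 measured nuclear photosynthesis genes had 0 calls and a median of -0.20 (camera adjusted p = 0.0156, and adjusted p = 0.663 with an estimated correlation), with PRK, of the Calvin cycle, at -0.41 and a list median of -0.13 without apum23 replicate 1. After quantile normalization PRK was called (-0.44, limma adjusted p = 0.0172), and the list did not pass (camera adjusted p = 0.142). None of the 11 mitochondrion-encoded genes was called, and their camera adjusted p was 0.294. Their largest difference was -0.38, for nad9, which was the only 1 called after quantile normalization (-0.51, limma adjusted p = 0.00334).

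Among smaller lists, 4 of 5 measured genes of flavonoid and anthocyanin synthesis rose and 0 fell. AT4G14090, an anthocyanin glucosyltransferase gene, rose by 0.85 and UF3GT, another anthocyanin glycosyltransferase gene, by 0.78 (limma adjusted p = 0.00424 and 0.012). The number that rose was 2 without wild-type replicate 1, apum23 replicate 1 or apum23 replicate 2, and 0 without apum23 replicate 3. The list's camera test gave an adjusted p = 0.0023, and adjusted p = 0.561 with an estimated correlation. Both measured genes of the salicylic acid and pathogen list rose: WRKY53, a transcription factor gene of defence and leaf senescence, from 5.07 ± 0.74 to 6.82 ± 0.19, and SAG101, a partner of EDS1, from 3.87 ± 0.40 to 4.75 ± 0.34. SAG101 was not called without apum23 replicate 1 or 3. With 2 members that list had no test. Of 4 measured genes of the abscisic acid, drought and cold list, the cold-regulated genes COR15A (0.84) and COR15B (0.72) rose and 2 did not pass (camera adjusted p = 0.294). Only COR15A was called without wild-type replicate 1 or without apum23 replicate 1, and neither was without wild-type replicate 2, apum23 replicate 2 or apum23 replicate 3. The 3 measured auxin genes had 0 calls and a median of -0.44 (camera adjusted p = 0.00883, and adjusted p = 0.561 with an estimated correlation). IAA29 was called without wild-type replicate 1 (-0.72) and without apum23 replicate 3 (-0.80). After quantile normalization all 3 fell, with IAA29, an auxin-induced repressor gene, at -0.75 (limma adjusted p = 0.000748).

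No member passed the test in the lists for leaf polarity (YAB5 at 0.27), jasmonate (PDF1.2 at 0.59), heat shock (AT5G37670 at -0.49), cell division (PRL at -0.31), DNA damage (SIM at -0.31), glucosinolates (BCAT4 at 0.06), iron and phosphate (BHLH101 at 0.35), the circadian clock (GI at 0.46), sugar response (APL3 at 0.11) or the Pumilio family (AT5G64490 at -0.01). Each of these lists had 1 to 3 measured members. After quantile normalization 5 of them had 1 called member each: GI was higher (0.41), and THI2.1 of the jasmonate list (-0.59, named after its values were seen), AT5G37670 (-0.59), PRL (-0.41) and SIM (-0.46) were lower, with limma adjusted p from 0.00871 to 0.0195. AT5G37670 was also called without wild-type replicate 1 (-0.75), while THI2.1 fell without wild-type replicate 1 (-0.66), and PDF1.2 (1.05) and PDF1.2b (0.90, named after its values were seen) rose without wild-type replicate 3. Markers of tissues and cell types were not called either. EXPA7 and EXPA18 of root hairs were at 0.01 and 0.26, and CLV3 of the shoot meristem at 0.19. MUTE, FMA and SPCH of the stomatal lineage were at 0.20, 0.13 and -0.08. After quantile normalization EXPA7 was at -0.12 and FMA at -0.0087, and neither was called. The lists for flowering, senescence, flower, seed and vasculature had no measured member and are not analysed here.

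The control probe set for 25S ribosomal RNA was brighter in apum23, at 5.33 ± 0.96 against 3.75 ± 0.30 in wild type (log2 difference 1.58, limma adjusted p = 1.14e-09). Its values were 5.85, 4.22 and 5.91 on the apum23 arrays and 3.84, 3.41 and 3.99 on the wild-type arrays. The wild-type mean lay within the range of the arrays' lower quartiles (3.41 to 3.84), so the size of the difference is uncertain. After quantile normalization the difference was 1.405 (limma adjusted p = 0.0222). The 5S ribosomal RNA probe set differed by -0.12 (limma adjusted p = 0.978). As a sign of RNA quality, the 3′ minus 5′ difference of actin was 1.59 ± 0.07 in wild type and 1.42 ± 0.08 in apum23 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). For GAPDH the exact permutation p was 0.5, and for ubiquitin 0.1.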

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

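The test and its threshold, the scale of the arrays and the choice of arrays all moved the counts. The tests on quantile-normalized values without wild-type replicate 1, with an estimated correlation or with fry, and median centring with a fold change threshold, were chosen after seeing the data. The cause was not tested for any change below unless a reason is given. None of the 36 called named genes changed direction in any setting that covered it. All 36 stayed called under quantile normalization and 31 to 36 with each array left out. For all 36 the groups did not overlap, so leaving arrays out could not reverse a direction and does not test it. With apum23 replicate 1 alone 28 were called, but there the spread comes from the wild-type arrays only and the lone mutant array is assumed to vary like them, so these calls say little about stability. The 2 ribosome lists kept a positive median in every setting run.

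Against 1522 calls, the count was 4481 under quantile normalization, 2997 with arrays centred on their medians (372 of them at an absolute log2 fold change of 1 or more), 3717 under quantile normalization without wild-type replicate 1, and 852 to 1842 with each array left out. It was 861 without wild-type replicate 2 and 880, 898 and 852 without apum23 replicates 1, 2 and 3. It was 253 with apum23 replicate 1 alone, 452 at an absolute log2 fold change of 1 or more, 170 with treat against 1.5-fold, 916 at an adjusted p under 0.01, and 895 with only 1-gene probe sets, where fewer were tested. An ordinary t-test without moderation left 2. Array weights gave 18930, but their estimate did not converge. Wild-type replicate 2 had a weight of 104.5 and apum23 replicate 2 of 25.1, against 0.0844 to 0.183 for the other arrays. That fit is close to a comparison of 1 array with 1, so neither this count nor any other result with array weights is usable as evidence. Called ribosomal protein genes numbered 103 under quantile normalization, 91 when wild-type replicate 1 was also left out, 119 with array weights, where 5 more were lower, 6 with apum23 replicate 1 alone, and 26 to 68 with each array left out. Called biogenesis factors numbered 4 with apum23 replicate 1 alone.

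Deviations of same-numbered arrays correlated at -0.29, 0.11 and 0.16, and 2 of the 6 arrays correlated best with their own number. This gives no sign of pairing, but such a correlation leaves out any overall shift of an array. Array medians rose with replicate number in both genotypes (5.34, 5.77 and 5.94 in wild type, 5.70, 5.75 and 6.10 in apum23), so pairing is not excluded. With the replicate block 2604 probe sets were called (1949 higher, 655 lower) and 86 ribosomal protein genes. The block changed no list call in limma's camera test, and it added calls for AT4G17560 (adjusted p = 0.04996) and IAA29 (adjusted p = 0.0213).

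The 6 lists with at least 5 measured members that passed camera did not pass with an estimated correlation or with fry, where the medians are unchanged by construction: ribosomal proteins (median 0.61, fry adjusted p = 0.131), biogenesis factors (1.01, 0.119), flavonoids (0.77, 0.238), plastid ribosomal proteins (-0.26, 0.521), photosynthesis (-0.20, 0.356) and plastid-encoded genes (-0.15, 0.523). On the deposited values no tested list passed with an estimated correlation or with fry, so these tests did not tell lists apart there. The estimated correlation was high there even for cell division (0.86), a list without a change. On quantile-normalized values with an estimated correlation, plastid ribosomal proteins (-0.30, adjusted p = 0.195), photosynthesis (-0.19, adjusted p = 0.327), flavonoids (0.59, adjusted p = 0.195) and plastid-encoded genes (-0.21, adjusted p = 0.677) did not pass, and both ribosome lists did. For plastid-encoded genes the estimated correlation stayed high, at 0.58 as deposited and 0.65 after quantile normalization. With fry on quantile-normalized values 5 of the 6 passed (adjusted p = 2.42e-05 for ribosomal proteins, 8.02e-05 for biogenesis factors, 0.00837 for plastid ribosomal proteins and for photosynthesis, 0.0178 for flavonoids), and plastid-encoded genes did not (adjusted p = 0.433). Auxin genes (adjusted p = 0.00465), mitochondrion-encoded genes and heat shock genes (adjusted p = 0.0446 for both, direction down) also passed that test, but not camera with an estimated correlation on the same values (adjusted p = 0.190, 0.331 and 0.677). In limma's camera test photosynthesis also did not pass under quantile normalization (-0.19, adjusted p = 0.142), with array weights (-0.19, adjusted p = 0.181), with apum23 replicate 1 alone (-0.33, adjusted p = 0.058) and under quantile normalization without wild-type replicate 1 (-0.18, adjusted p = 0.161), nor did plastid-encoded genes in the last of these (-0.11, adjusted p = 0.0773). In limma's camera test with array weights, plastid ribosomal proteins (-0.25, adjusted p = 0.119) and flavonoids (0.38, adjusted p = 0.135) did not pass, while the abscisic acid, drought and cold list did (0.64, adjusted p = 0.0017). As the weights did not converge, these results and that for photosynthesis with array weights count neither for nor against a list.

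Signs changed only for lists and genes that were not called on the deposited values. Medians under quantile normalization were -0.049 for leaf polarity, -0.071 for heat shock, -0.0087 for epidermis markers and -0.089 for mitochondrion-encoded genes, with camera at both correlations and with fry. There APL3 was at -0.041, EXPA7 at -0.12 and FMA at -0.0087, the median of the 2 root markers, 0.13 as deposited, was -0.012, and that of the 2 glucosinolate genes, 0.018 as deposited, was -0.022. With median centring leaf polarity was at -0.10, heat shock at -0.092, cell division at -0.0020, epidermis markers at -0.037, mitochondrion-encoded genes at -0.16, BCAT4 at -0.11, APL3 at -0.060, EXPA7 at -0.16 and FMA at -0.037. With array weights, which did not converge, cell division was at -0.12, mitochondrion-encoded genes at -0.13, BCAT4 at -0.30, APL3 at -0.12, CLV3 at -0.083, EXPA7 at -0.064, FMA at -0.16 and SPCH at 0.024. With apum23 replicate 1 alone leaf polarity was at -0.20, heat shock at -0.23, epidermis markers at -0.17, mitochondrion-encoded genes at -0.23, YAB5 at -0.20, BCAT4 at -0.063, BHLH101 at -0.033, APL3 at -0.19, MUTE at -0.17, CLV3 at -0.038 and EXPA7 at -0.24. Under quantile normalization without wild-type replicate 1, jasmonate was at -0.14, heat shock at -0.014, mitochondrion-encoded genes at -0.15, BCAT4 at -0.11, APL3 at -0.13 and EXPA7 at -0.061. With each array left out, ranges were -0.071 to 0.070 for AT5G64490, -0.22 to 0.23 for BCAT4, -0.15 to 0.29 for APL3, -0.10 to 0.14 for EXPA7, -0.020 to 0.24 for FMA, -0.25 to 0.20 for SPCH, -0.23 to 0.90 for jasmonate, -0.0063 to 0.24 for heat shock, -0.026 to 0.29 for cell division, -0.020 to 0.20 for epidermis markers and -0.12 to 0.10 for mitochondrion-encoded genes. Set tests with the trend and robust variance model were not run.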

Other observations

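The gene families and the tests of direction, of 25S ribosomal RNA against array scale and RNA quality, of the families as sets and of large rises among bright and dim genes were chosen after the values were seen. For 7 tests the bound that decides the reading was also changed after its result was known: the RNA quality, array-scale and equally dim probe set tests of 25S ribosomal RNA, the tests of both families, the direction of all calls and signal compression. What the first bounds gave is stated with each, and under the changed ones all 7 explanations stay open.

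The following families were chosen because called members had been seen. Of 12 measured genes with NRP symbols, for subunits of the nuclear RNA polymerases, 6 rose, 0 fell and 6 did not pass limma's test, with NRPA2 and NRPA1, the large subunits of RNA polymerase I, at 1.18 and 1.15, NRPC1 and NRPC2 of RNA polymerase III at 0.77 and 0.71, NRPB12 at 1.01 and NRPD7 at 0.75. NRPA1 and NRPA2 are on the ribosome biogenesis list and already counted among its 33, and 4 of the other 10 rose. Of 13 measured genes of the chloroplast NAD(P)H dehydrogenase complex, 7 fell, 0 rose and 6 did not pass: the plastid genes ndhK (-0.95), ndhJ (-0.86), ndhE (-0.81), ndhD (-0.68) and ndhG (-0.67) and the nuclear genes NdhL (-0.92) and NdhN (-0.73). The 5 plastid genes are among the 9 called plastid-encoded genes. That list had 1 call without wild-type replicate 2 or without apum23 replicate 2, and 3 without apum23 replicate 1. It had 6 to 11 with each other array left out. ALN and AAH, which act in successive stages of ureide breakdown, were at -1.45 and -0.99 (limma adjusted p = 1.88e-08 and 0.000508).

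As a hypothesis, each of these families may have moved as a set. On quantile-normalized values the NDH family had a median of -0.76, below the lowest of 10000 random sets matched on brightness (-0.42), and the NRP family had a median of 0.55, above the highest (0.39). Under the first bound, which asked only for this, both families passed. The random sets were drawn from all named genes, while 10 of the 13 NDH genes are plastid-encoded, and that list was itself lower. On the same values those 10 had a median of -0.60, with 5 called lower. The 59 other plastid-encoded genes had a median of -0.20, with 12 called lower. Without NRPA1 and NRPA2 the NRP median was 0.46, with 99.99% of matched sets lower but the highest at 0.51. Because called members had prompted the choice, the bound was then made stricter, to require the same of the members that were not called. By that bound both stay open. The 6 NDH genes uncalled on the deposited values had a median of -0.15, with 11.7% of matched sets lower. The 6 NRP genes uncalled there had a median of 0.31, with 98.8% lower. Of these genes NdhS, NRPB6A and NRPB6B were called on the quantile-normalized values (limma adjusted p = 0.0187, 0.0076 and 0.0392). Leaving out called members biases this second test against a set, and neighbouring plastid genes share transcripts, so neither reading settles it.

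Most calls were higher in apum23, and part of this may come from array scale. After quantile normalization 49.2% of all calls were higher, and 39.9% with arrays centred on their medians. The first bound, a share near even, had read the quantile-normalized share as what that explanation needs. Quantile normalization itself moves the balance toward even, and median centring took it past even, to mostly lower calls. How far a scaling alone would move the balance was not tested, so these shares leave it open. Among calls of 2-fold or more 74.6% were still higher after quantile normalization (exact binomial 95% interval 69.9 to 78.9, with genes not independent) and 64.0% after median centring (58.9 to 68.9). The lower limit after quantile normalization met the bound for evidence against scale as the whole cause there. After median centring it fell short of that bound. The intervals are too narrow for genes that move together, so this does not settle it. The 6 arrays have only 10 splits, too few for a share under 0.05. The real split gave 1522 calls and the highest other split 34, and after quantile normalization 4481 and 0. For called ribosomal protein genes the values were 56 and 0, and for biogenesis factors 33 and 0. In each case 1 split, the real one, gave a result as large. Every other split mixes the genotypes within its groups, so a genotype difference would add to the spread there and lower those counts. They do not show what chance alone would give.

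Among ribosomal protein genes with a mean of 5 or more, dim ones rose more than bright ones. On quantile-normalized values the median log2 fold change was 1.04 for 15 members with a mean under 8.5 and 0.49 for 83 with a mean of 10 or more, a ratio of 0.47 (bootstrap 95% interval 0.29 to 0.66). The 13 members with a mean under 5 had 0 calls in limma's test and a median of 0.08, and with them the 28 dim members had a median of 0.60 and the ratio was 0.82 (0.52 to 4.70), so the pattern rests on leaving them out. Compression of bright signals stays open. The 5th to 95th percentile spread of other bright genes was 0.97 of that of dim ones, which the first bound read as evidence against it. Without the floor of 5 the spread ratio was 1.21. The dim group then takes in probe sets close to the background, where changes can go unseen, so this ratio cannot show compression or its absence. The ribosomal interval then includes 1, but the 13 added members may be too dim to show a rise, so it decides nothing. Large rises were rarer among other bright probe sets, where the 99th percentile of log2 fold changes was 0.70 of that of dim ones. Of 890 bright ones 3 rose by 1 or more, against 187 of 10248 dim ones. Cross-hybridization between paralogs was not tested, and a response that differs between paralogs stays open as a hypothesis.

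The 25S ribosomal RNA signal was higher in apum23 on an oligo(dT)-primed array. Its wild-type mean of 3.75 lay within the range of the arrays' lower quartiles, and a probe set so close to the background excludes nothing. After quantile normalization the difference was 1.405 with a standard error of 0.37, and of 3775 probe sets of like wild-type level 0.662% rose as much. The first bounds (a difference above 0.5, and under 1% of such probe sets) had read these as evidence against array scale and against the spread of dim probe sets, and both stay open. RNA quality stays open: the mean 3′ minus 5′ difference over actin, GAPDH and ubiquitin differed by -0.11 between apum23 and wild type (95% interval -0.23 to 0.02, exact permutation p = 0.2), where the first bound of 2 standard errors had read it as evidence against poorer RNA. Whether more polyadenylated ribosomal RNA, known from mutants in its processing, is a candidate source was not tested.

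Called genes might cluster along chromosomes, as AGL19 (2.33) and its neighbour AT4G22960 (2.15) do. Of 5845 adjacent measured pairs, 25 were called the same way, between the median of 10000 permutations (19) and their 95th percentile (26), which leaves this open. Near APUM23 itself, 1 of 22 measured genes among 20 neighbours on each side was called (4.55%), against 6.83% of all measured nuclear genes. This gives no sign of a change of that region, but 22 genes are too few to exclude one. The called gene was AT1G72230 at -0.91.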
